A study of Mus musculus with 20 samples.

How the data were processed

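Nuclei from mouse spinal cord were sorted by flow cytometry on NeuN, a nuclear protein of neurons, per the labels' protocols. RNA of the NeuN-positive and NeuN-negative nuclei was sequenced from healthy mice and from mice with experimental autoimmune encephalomyelitis (EAE) 15 days after active immunization. RNA was purified on Qiagen columns and libraries were made from polyadenylated RNA with an Illumina TruSeq kit, per the labels' protocols. The deposited values are raw counts per Ensembl gene in a single table of the whole series, with a column per library and no normalization. STAR 2.4 and DESeq2 are named among the tools and GRCm39 and mm10 among the genome builds, per the submitters' processing notes, which give no role for either build. The counting tool, the annotation release and the use of strand are not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart, and gene positions are given from the GENCODE M21 annotation of GRCm38 by gene identifier.

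The table held 43629 genes, of which 5168 were at 0 in all 20 libraries, 42462 carried a symbol and 1167 did not. The genes without a symbol took 0.2515 to 0.4144% of the counts of a library and stayed in the library totals. Totals ran from 3149209 to 37689267 counts. The 40 pairs of libraries within groups were compared by a chi-square over genes with at least 20 counts in the pair. Its value per gene was 11.1 to 392.8, and 0 pairs held identical values. Healthy replicates 1 and 2 were the closest pair in both sorts, at 11.1 (NeuN-positive) and 16 (NeuN-negative). Each library was counted as a separate sample, although these values do not show that the libraries come from separate mice.

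Groups were taken from the titles, with 5 libraries each. Each comparison was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM normalization, a quasi-likelihood fit with robust dispersion, and Benjamini-Hochberg adjustment over the genes tested, with a gene called at an adjusted p under 0.05. Each EAE and each sort comparison was fitted on its own 10 libraries, and the difference of the EAE effect between the sorts on all 20 libraries. Log2 fold changes are given with their standard errors, and CPM (counts scaled to library size with TMM over the 20 libraries) as mean ± SD. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 40 lists of a comparison, of which 23 hold pathway or quality genes and 17 cell type markers. Of the 973 list entries, 951 were found in the table, including older and newer symbols of the same gene. A fold against a group at 0 in every library was computed against a floor of 3 counts over the group, which covers counting error only. Library measures were compared by exact permutation tests, two-sided, over 252 regroupings, where the smallest possible p is 0.00794.

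The genes named in the text were chosen by a rule set before the data were examined. It takes 8 fixed genes and the 8 largest rises and 8 largest falls of each EAE comparison. These come from called genes with a mean log2 CPM of at least 1, a proper symbol and no overlap between the groups' libraries. It also takes the 5 largest each way for the other comparisons, and up to 2 rising and 2 falling members of each list by smallest p. Not all of them are printed, and 5 genes are not reported here. The lists, tests and alternatives were also set before the data were examined, except those named as added. The alternatives were DESeq2 1.42.0 size factors in edgeR, the DESeq2 Wald test, limma voom with quality weights, no count filter, and a filter of at least 1 CPM in at least 5 libraries. Others were a minimum change of 2-fold, the replicate number as a block, a fit on all 20 libraries, and oligodendrocyte marker level as a covariate. Each library was also left out in turn, correlations were estimated per list, and the mitochondrial share was recomputed without the 10 most abundant genes. Added after the data were seen were a fit without the 3 mice whose NeuN-positive library held over 2% mitochondrially encoded counts (EAE 2, EAE 4 and healthy 3), the mitochondrial share as a covariate, removal of each library's GC trend, and omission of Gm10800, Gm10801 and the mitochondrial genes. Members of the lists were also counted without these mice, and the list tests were run with DESeq2 size factors.

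The titles number libraries 1 to 5 in every group. Deviations from the group means of the NeuN-positive and NeuN-negative libraries of a number correlated at 0.115 to 0.379 in the 5 EAE pairs and at 0.28 to 0.7 in the 5 healthy pairs, all over 0.1, the limit set for this check, so the numbers were taken to pair the sorts. Libraries of different numbers reached 0.187 in EAE and 0.32 in healthy mice, and healthy 2 correlated more with another number (0.288) than with its own (0.28), so the pairing is an assumption. The replicate block for these comparisons is given where it changed the call of a list or a named gene or moved a count by over 1.5 times. In simulated data with known changes, the test of NeuN-positive nuclei recovered 18% of the genes changed by 1 log2 unit and 74% of those changed by 2. Of its 97 calls among 16242 genes 5 were false. For NeuN-negative nuclei the shares were 3% and 66%, for the difference between the sorts 0% and 19%, for the sorts of healthy mice 17% and 72%, and for those of EAE mice 0% and 55%. False calls in these 4 comparisons were 3 of 72, 1 of 20, 4 of 93 and 7 of 62. Genes were simulated independently of each other and without quality differences between the groups. The labels do not say that each library comes from a separate mouse, so the p-values measure the spread between these samples, part of which may be technical.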

Results

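Gene expression was measured in nuclei of mouse spinal cord sorted into NeuN-positive nuclei, mainly of neurons, and NeuN-negative nuclei, mainly of other cells. The mice were healthy or had EAE, an autoimmune inflammation of the central nervous system used as a model of multiple sclerosis, at day 15 after active immunization. Each of the 4 groups held 5 libraries. Total counts per library ran from 12076860 to 30499828 in healthy NeuN-positive and from 7072200 to 18686997 in EAE NeuN-positive nuclei. They ran from 8336330 to 37689267 in healthy NeuN-negative and from 3149209 to 15525441 in EAE NeuN-negative nuclei. Mitochondrially encoded transcripts, which come from cytoplasm, took 0.910% ± 1.20 (SD, n = 5) of counts in healthy and 3.61% ± 3.68 in EAE NeuN-positive libraries (exact permutation test, two-sided, p = 0.167, adjusted p = 0.18). In NeuN-negative libraries they took 1.79% ± 1.67 and 7.89% ± 4.77 (exact permutation test, two-sided, p = 0.0159, adjusted p = 0.074). None of the 14 comparisons of library measures passed adjustment, and the lowest adjusted p was 0.074. The smallest possible p is 0.00794 (exact permutation test, two-sided), so no measure could pass alone, and equal library quality is not shown. Unadjusted p was under 0.05 (exact permutation tests, two-sided) for olfactory and vomeronasal receptor genes and for Gm10800 and Gm10801 in both sorts. The same held in NeuN-negative libraries for the 10 most abundant genes, the genes detected and the mitochondrial share. These were all higher in EAE, and it held for no other comparison.

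**Figure D1:**
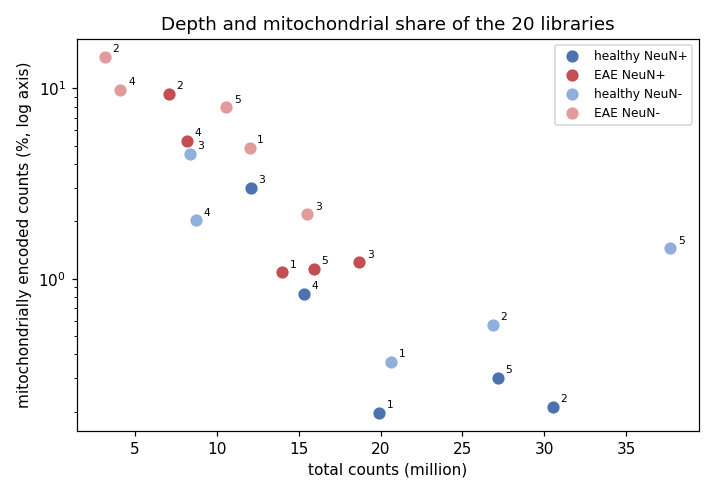
Total counts per library (x axis, scaled as labelled) against the percent of mitochondrially encoded counts (y axis, log scale) for the 20 libraries, with the replicate number beside each point and the 4 groups in different colours. The library with the fewest counts, EAE NeuN-negative replicate 2 with 3149209, also had the highest share, 14.64%.

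The sort was checked in healthy mice first. Rbfox3, which encodes NeuN, was higher in NeuN-positive nuclei by 3.42 ± 0.30 on the log2 scale (SE, 5 against 5 libraries; adjusted p = 2.53e-06), at 313 ± 33.3 against 29.7 ± 10.7 CPM. Of the 16 neuron markers 12 were higher and 0 lower (13 adjusted over the list alone), among them Snhg11, a neuronal long noncoding RNA, by 4.28 ± 0.33. All 14 microglia markers, 17 of 19 oligodendrocyte markers, all 16 astrocyte and all 16 endothelial markers were lower in NeuN-positive nuclei, with the same counts adjusted over the list alone. Examples were the microglial receptor gene Csf1r at -4.92 ± 0.28, the myelin gene Opalin at -5.20 ± 0.31 and Fgfr3, an astrocyte receptor gene, at -3.32 ± 0.28. Voltage-gated channel genes (35 of 41 higher, 3 lower, 36 and 3 adjusted over the list alone) and transmitter receptor genes (29 of 39 higher, 2 lower, 31 and 2 adjusted over the list alone) moved with the neuron markers. The largest differences under the naming rule were the rises of Vwa5b2 (4.58 ± 0.44), Coro6 (4.51 ± 0.34) and Hcrtr1, an orexin receptor gene (4.48 ± 0.62), and the falls of Nlrp1b, an inflammasome sensor gene (-6.27 ± 0.61), Fbxw15 (-6.21 ± 0.43) and Cyp3a13, a cytochrome P450 gene (-5.78 ± 0.38).

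In healthy mice 3910 genes were higher and 3938 lower in NeuN-positive nuclei among 17134 tested. Without the healthy 3 mouse, left out after the data were seen, the counts were 4512 and 4576. The camera test called 6 lists higher, including neuron (adjusted p = 1.95e-05) and voltage-gated channels (2.45e-16), and 14 lower. With an estimated correlation only the lower microglia and oligodendrocyte lists kept an adjusted p under 0.05 (both adjusted p = 0.0319), while the neuron list had adjusted p = 0.203 and the channel list adjusted p = 0.102 with an estimated correlation. With the replicate block, MHC class I (0.047 without it) had adjusted p = 0.0582 and neutrophil (0.0345 without it) 0.133, while the mitochondrially encoded list went from 0.464 to 0.0233. Signs of median, mean and camera direction differed for the uncalled standard proteasome, immediate-early and axon injury lists.

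In EAE mice the same comparison gave Rbfox3 higher in NeuN-positive nuclei by 2.60 ± 0.40 (adjusted p = 0.00018), at 194 ± 58.5 against 29.7 ± 15.8 CPM. Neuron markers were higher for 14 of 16 genes (14 adjusted over the list alone), for example Dnm1, a synaptic vesicle endocytosis gene, by 3.51 ± 0.47. Microglia markers were lower for 13 of 14 (14 adjusted over the list alone), oligodendrocyte markers for 15 of 19 (16), T cell markers for 13 of 21 with 1 higher (15 and 1), and interferon-stimulated genes for 57 of 73 (59). Tmem119, a microglial surface gene, was at -2.59 ± 0.37. Psmb9 and Psmb8, subunits of the immunoproteasome, were at -1.68 ± 0.46 and -1.37 ± 0.41. Among the largest differences were rises of Sptbn4, a spectrin gene of the axon initial segment (4.60 ± 0.50), and P2rx6, a purinergic receptor gene (4.61 ± 0.43), and the fall of Tlr9, an endosomal DNA sensor gene (-5.34 ± 1.09). In all, 2793 genes were higher and 2662 lower among 17982, and 3787 and 3768 without the EAE 2 and EAE 4 mice. The camera test called 7 lists higher and 20 lower, and 0 and 0 with an estimated correlation, where neuron had adjusted p = 0.055, microglia adjusted p = 0.141, T cell adjusted p = 0.153 and interferon-stimulated genes adjusted p = 0.218 with an estimated correlation. With the replicate block the immunoproteasome list went from adjusted p = 0.0493 to 0.0696 and the mitochondrially encoded list from 0.0627 to 0.00135. Signs of median, mean and camera direction differed for the uncalled glycolysis and motor neuron lists. DESeq2 size factors moved the median of all genes by -0.102 on the log2 scale here.

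The study is about immunoproteasomes induced by interferon and about neuronal metabolism. The comparison of NeuN-positive nuclei between EAE and healthy mice bears on both only as far as its RNA comes from neurons. Immune cell markers were also higher in these EAE libraries, as given below. The 3 inducible catalytic subunits of the immunoproteasome, the proteasome form that shapes peptides for MHC class I, rose in EAE, each higher in all 5 EAE libraries than in any healthy library. Psmb9 (ENSMUSG00000096727, chromosome 17, 34181987 to 34187764, minus strand) went from 0.905 ± 0.297 to 28.5 ± 9.54 CPM (n = 5 and 5), a log2 fold change of 5.09 ± 0.38 (adjusted p = 6.63e-06). Its annotated span shares 212 bases with Tap1 on the plus strand. Psmb8 (ENSMUSG00000024338, chromosome 17, 34197721 to 34201454, plus strand) went from 2.47 ± 1.30 to 53.9 ± 21.4 CPM, a log2 fold change of 4.55 ± 0.42 (adjusted p = 2.19e-05). Psmb10 (ENSMUSG00000031897, chromosome 8, 105935735 to 105938444, minus strand) went from 33.1 ± 13.8 to 115 ± 37.3 CPM, a log2 fold change of 1.88 ± 0.34 (adjusted p = 0.00287). The standard catalytic subunit genes Psmb5, Psmb6 and Psmb7 were not called, with log2 fold changes of 0.40 ± 0.33, 0.14 ± 0.24 and 0.23 ± 0.35 (adjusted p = 0.455, 0.744 and 0.7).

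**Figure D2:**
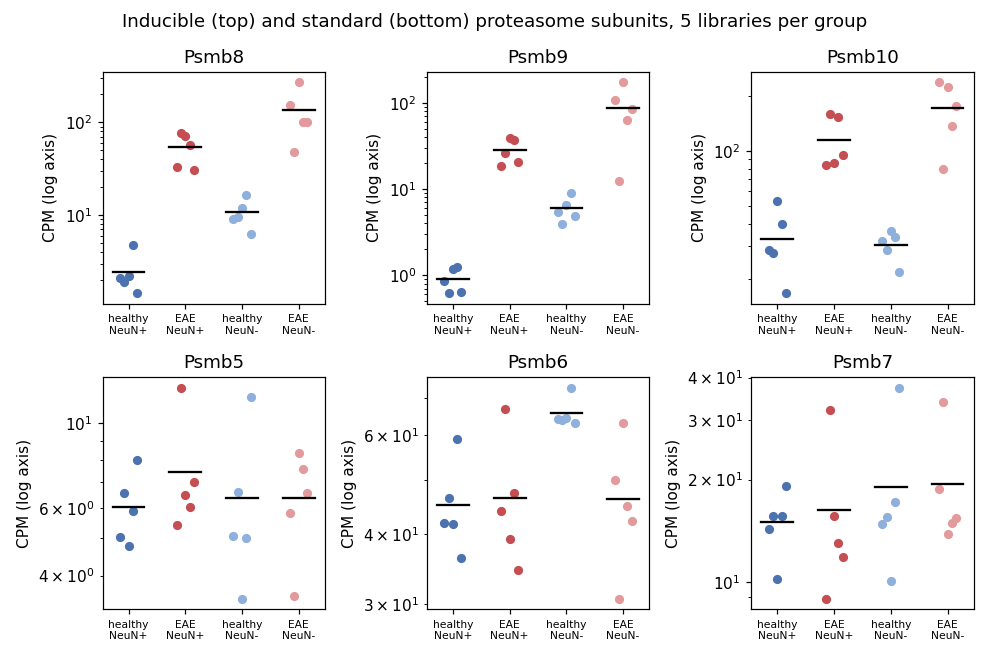
CPM (log axis) of the inducible subunit genes Psmb8, Psmb9 and Psmb10 (top) and the standard subunit genes Psmb5, Psmb6 and Psmb7 (bottom) in each of the 5 libraries (points) of the 4 groups (x axis), with the mean as a horizontal line. In NeuN-positive nuclei the mean of Psmb9 was 0.905 CPM in healthy and 28.5 CPM in EAE mice, and that of Psmb6 was 45.0 and 46.4 CPM.

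The immunoproteasome list as a whole, with the PA28 activator genes, had 3 of 5 members higher and 0 lower (3 adjusted over the list alone; camera adjusted p = 7.61e-09, and 0.0312 with an estimated correlation). Interferon-stimulated genes rose for 59 of 68 members (66 adjusted over the list alone; camera adjusted p = 1.41e-71), for example Iigp1, a GTPase gene of defence against intracellular pathogens, by 6.63 ± 0.53 and Irgm2, of the same family, by 5.30 ± 0.43. MHC class I presentation genes rose for 14 of 18 (15 higher and 1 lower adjusted over the list alone), with the class I heavy chain H2-K1 at 5.22 ± 0.34 and the peptide transporter Tap1 at 4.42 ± 0.35. MHC class II genes rose for 6 of 9 (8 adjusted over the list alone), among them Ctss, a lysosomal protease gene, at 6.19 ± 0.65. In the same libraries markers of immune cells were higher. These were 14 of 18 markers of monocytes and macrophages (16 adjusted over the list alone) and 8 of 9 of neutrophils (8 adjusted over the list alone). They also were 9 of 13 of T cells (10) and 4 of 13 of microglia (9). Lyz2 of macrophages went from 6.31 to 521 CPM, S100a9 of neutrophils from 0.122 to 18.8 CPM, Cd4 from 0.565 to 10.4 CPM and Csf1r from 6.66 to 60.7 CPM. The mean CPM of Psmb9, Psmb8 and H2-K1 in NeuN-negative nuclei of the EAE mice was 88.6, 135 and 1520, against 28.5, 53.9 and 513 in NeuN-positive nuclei. Monocyte and neutrophil lists kept an adjusted p under 0.05 with an estimated correlation (0.0397 and 0.0421), while T cell and microglia lists had adjusted p = 0.141 each with an estimated correlation.

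Other inflammatory groups rose as well. Reactive astrocyte genes rose for 26 of 30 members (28 adjusted over the list alone). Activated microglia and phagocyte genes rose for 23 of 30 (30), with Ccl6, a chemokine gene, at 6.55 ± 0.63 and Arg1, the arginase of phagocytes, at 6.45 ± 0.60. Cytokine, chemokine and complement genes rose for 15 of 20 (16 higher and 1 lower), with the complement gene C1qc at 4.45 ± 0.36. With an estimated correlation the reactive astrocyte and cytokine lists had adjusted p = 0.0228 and 0.0361, and the phagocyte list adjusted p = 0.061. Among the largest rises were Cxcl9, a chemokine gene induced by interferon gamma (8.13 ± 0.91), Saa3, an acute phase gene (7.97 ± 0.94), and Chil3, a gene of activated macrophages (7.53 ± 1.10). Clec4d, a myeloid lectin gene, had 0 counts in the 5 healthy libraries and 439 in the 5 EAE libraries, at least 232-fold higher against a floor of 3 counts over the group. Cell death effector genes rose for 7 of 27 and fell for 1 (11 and 2 adjusted over the list alone), with Zbp1, a sensor gene that triggers necroptosis, at 5.87 ± 0.61 and Aifm1, a mitochondrial flavoprotein gene, at -1.68 ± 0.47. Axon injury genes rose for 8 of 32 (11 higher and 4 lower adjusted over the list alone), with the stress transcription factor gene Atf3 at 3.04 ± 0.45, and immediate-early genes for 6 of 21 (8 and 2). Cell cycle genes rose for 4 of 34 (4), led by Top2a at 4.86 ± 0.75. These 4 lists lost their call with an estimated correlation (cell death adjusted p = 0.351, axon injury adjusted p = 0.394, immediate-early adjusted p = 0.362, cell cycle adjusted p = 0.344). Without the 3 mice 3 of 22 immediate-early genes (median 0.28 against 0.77), 6 of 35 cell cycle genes, 7 of 14 microglia and 14 of 19 T cell markers were higher.

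Of the metabolic groups, glycolysis genes rose for 2 of 24 and fell for 1 (2 and 2 adjusted over the list alone; camera adjusted p = 0.832). Hk2, an inducible hexokinase gene, rose by 3.69 ± 0.51 and Ldha, lactate dehydrogenase A, by 1.36 ± 0.24, while Eno1, an enolase gene, had -0.89 ± 0.24 (adjusted p = 0.0336). Hk2 and Ldha also rose in NeuN-negative nuclei, and which cells gave their rise here was not tested. Pfkfb3 (ENSMUSG00000026773, chromosome 2, 11471433 to 11554077, minus strand), which encodes an activator of glycolysis, was at 56.8 ± 7.47 and 50.6 ± 13.3 CPM, a log2 fold change of -0.09 ± 0.21 (adjusted p = 0.809). Nuclear-encoded oxidative phosphorylation genes rose for 8 of 75 and fell for 3 (15 and 4 adjusted over the list alone; camera adjusted p = 0.00234, and adjusted p = 0.706 with an estimated correlation), with the complex I genes Ndufb3 at 1.81 ± 0.40 and Ndufv1 at -1.41 ± 0.30. Without the 3 mice with a high mitochondrial share these counts were 1 and 0. Of the 9 mitochondrially encoded transcripts tested 0 were called (0 adjusted over the list alone), with a median log2 fold change of 2.12 (camera adjusted p = 0.00316, and adjusted p = 0.563 with an estimated correlation). Without the 3 mice 5 of the 9 were higher, with a median of 1.81. Antioxidant genes rose for 9 of 29 (9 adjusted over the list alone), led by the metallothionein genes Mt2 (3.17 ± 0.37) and Mt1 (2.64 ± 0.36), with camera adjusted p = 0.000731 and adjusted p = 0.394 with an estimated correlation. Pentose phosphate genes had 0 of 10 called (0), and cholesterol synthesis genes had 2 of 23 lower (2), among them the reductase gene Tm7sf2 at -1.15 ± 0.32.

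Among neuronal genes, 4 of 41 voltage-gated channel genes fell and 1 rose (5 and 1 adjusted over the list alone; camera adjusted p = 0.0057, and adjusted p = 0.38 with an estimated correlation). Cacna1h, a T-type calcium channel gene, fell from 214 ± 21.7 to 62.2 ± 38.2 CPM (-1.71 ± 0.31, adjusted p = 0.00286), while Scn9a, a sodium channel gene, rose by 1.03 ± 0.29. Synaptic release genes fell for 5 of 33 and rose for 1 (5 and 1), with the vesicle priming gene Unc13a at -1.32 ± 0.31 and the SNARE gene Stx1a at -1.20 ± 0.30. Transmitter receptor genes fell for 2 of 40 and rose for 1 (2 and 0), with Grik1, a kainate receptor gene, at -2.10 ± 0.56. Markers of inhibitory neurons fell for 2 of 13 (4 lower and 1 higher adjusted over the list alone), the GABA transport and synthesis genes Slc32a1 (-1.15 ± 0.31) and Gad1 (-0.73 ± 0.21). Those of excitatory neurons fell for 2 of 14 (2), the neuropeptide gene Tac2 (-2.17 ± 0.35) and the transcription factor gene Lmx1b (-1.39 ± 0.29). None of the 16 general neuron markers was called (0 adjusted over the list alone), and Rbfox3 (ENSMUSG00000025576, chromosome 11, 118489762 to 118911597, minus strand) had a log2 fold change of -0.62 ± 0.22 (adjusted p = 0.0918). Rbfox3 was called lower in 3 alternatives, DESeq2 Wald (adjusted p = 0.0489), voom (0.000223) and without EAE NeuN-positive 3 (0.0398). The largest falls included Rhbdl1, a rhomboid protease gene (-3.57 ± 0.93), Doc2a, a calcium sensor gene of transmitter release (-2.96 ± 0.45), Zfp335 (-2.52 ± 0.49) and the antisense gene Grin1os (-2.59 ± 0.48), whose reads cannot be told from those of its sense partner. Without the 3 mice with a high mitochondrial share, 2 channel genes, 2 synaptic genes and 1 receptor gene were lower. Calls were lost in several of 22 alternatives, for Scn9a in 13, Gad1 in 12, Slc32a1, Grik1 and Tm7sf2 in 10 each, Eno1 and Aifm1 in 9 each, Rhbdl1 in 6 and Stx1a in 5.

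Standard proteasome genes rose for 4 of 34 and fell for 1 (5 and 2 adjusted over the list alone), with the assembly gene Pomp at 1.66 ± 0.34 and the cap subunit gene Psmd6 at -1.19 ± 0.28, and 1 and 0 without the 3 mice. Stress response genes rose for 4 of 33 and fell for 1 (5 and 1), with the transcription factor gene Atf4 at 1.19 ± 0.23, and heat shock genes for 1 and 1 of 14 (1 and 1), the chaperone genes Hspb1 (3.02 ± 0.44) and Dnajb1 (-1.08 ± 0.23). Among cell type markers the numbers higher and lower were 2 and 0 of 19 for oligodendrocytes (2 and 0 adjusted over the list alone) and 0 and 1 of 11 for their precursors (1 and 1). They were 3 and 2 of 16 for astrocytes (4 and 3), 1 and 0 of 7 for B cells (2 and 0) and 1 and 0 of 11 for ependymal cells (1 and 0). They were 1 and 0 of 10 for Schwann cells (1 and 0), 0 and 0 of 12 for motor neurons (0 and 0) and 0 and 0 of 3 for erythroid cells (0 and 0). Camera called none of these 8 lists. The signs of the median, the mean and the camera direction differed for B cell, stress response, glycolysis, neuron and motor neuron lists, none of them called. Endothelial markers rose for 2 of 16 (2; camera adjusted p = 0.0454, and adjusted p = 0.722 with an estimated correlation) and pericyte and fibroblast markers for 5 of 16 (6; camera adjusted p = 0.00691, and adjusted p = 0.563 with an estimated correlation).

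In all, 1092 genes were higher and 613 lower in NeuN-positive nuclei of EAE mice among 16675 tested, and 1013 and 462 changed by at least 2-fold. Without the EAE 2, EAE 4 and healthy 3 mice, left out after the data were seen, 1249 were higher and 317 lower. There 62 of 68 interferon-stimulated genes, 13 of 18 MHC class I genes and all 3 inducible subunits were higher. In the NeuN-positive libraries kept there the mitochondrial share was 1.079 to 1.218% in EAE and 0.1969 to 0.8332% in healthy mice. The groups did not overlap, so this fit does not part library quality from EAE. With the mitochondrial share as a covariate the counts were 528 and 166. Other tests called 2634 and 1412 (DESeq2 Wald) or 3823 and 3882 (limma voom). Leaving out a single library gave 677 (without healthy 2) to 1721 (without healthy 3) genes higher and 178 (without EAE 5) to 1462 (without EAE 3) lower.

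In NeuN-negative nuclei the comparison asks the same of the remaining cells. Markers of lymphocytes and phagocytes rose: 20 of 21 T cell markers (20 adjusted over the list alone), 10 of 14 B cell markers (12), 16 of 18 monocyte and macrophage markers (16 higher and 1 lower) and 9 of 10 neutrophil markers (9). Cd4, the helper T cell coreceptor gene, rose from 1.03 ± 0.541 to 37.1 ± 17.4 CPM (log2 fold change 5.46 ± 0.48, n = 5 and 5, adjusted p = 1.61e-06), Ccr2, a monocyte chemokine receptor gene, by 4.80 ± 0.35 and Cd22, a B cell gene, by 4.47 ± 0.38. All 4 lists kept an adjusted p under 0.05 with an estimated correlation, at 0.0183, 0.0419, 0.0183 and 0.0292. Microglia markers rose for 2 of 14 and fell for 1 (2 and 1; camera adjusted p = 0.893), with the chemokine receptor gene Cx3cr1 at 1.91 ± 0.44 and Fcrls at -2.27 ± 0.45. Oligodendrocyte markers fell for 13 of 19 and rose for 0 (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 3.19e-07, and 0.0419 with an estimated correlation). Opalin, a myelin membrane gene, fell from 254 to 18.8 CPM (-3.54 ± 0.42) and Fa2h, a myelin lipid enzyme gene, had -2.52 ± 0.44. Astrocyte markers fell for 8 of 16 (11), with the amino acid transporter gene Slc7a10 at -4.29 ± 0.64 and Ntsr2 at -3.67 ± 0.61, and precursor markers for 6 of 11 (7). These lists had adjusted p = 0.231 and adjusted p = 0.119 with an estimated correlation.

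All 5 immunoproteasome genes rose in NeuN-negative nuclei (5 adjusted over the list alone; camera adjusted p = 1.28e-06, and adjusted p = 0.119 with an estimated correlation), with Psmb9 at 4.07 ± 0.51, Psmb8 at 3.83 ± 0.44 and Psmb10 at 2.67 ± 0.34. Psmb5, Psmb6 and Psmb7 were at 0.27 ± 0.46, -0.28 ± 0.26 and 0.32 ± 0.39 and not called, nor was Pfkfb3 at -0.05 ± 0.33 (adjusted p = 0.916). Interferon-stimulated genes rose for 65 of 71 (68), MHC class I genes for 16 of 18 (17) and class II genes for 11 of 11 (11), led by Bst2, an antiviral tether gene (4.48 ± 0.36), H2-Q7 (5.28 ± 0.59) and H2-Aa (5.92 ± 0.47). These 3 lists had adjusted p = 0.0299, 0.043 and 0.0419 with an estimated correlation. Reactive astrocyte genes rose for 27 of 30 (27), phagocyte genes for 24 of 33 (29) and cytokine, chemokine and complement genes for 24 of 29 (25), and all 3 lists had adjusted p = 0.0183 with an estimated correlation. Cell cycle genes rose for 21 of 38 (24 higher and 1 lower), with the proliferation gene Mki67 at 4.32 ± 0.41 (0.0292 with an estimated correlation). Cholesterol synthesis genes fell for 13 of 24 and rose for 1 (14 and 1), with the final enzyme gene Dhcr7 at -1.91 ± 0.29 and the sterol sensor gene Insig1 at -2.02 ± 0.44 (camera adjusted p = 2.97e-05, and adjusted p = 0.164 with an estimated correlation). Oligodendrocyte and astrocyte markers fell in these libraries while immune cell markers rose. Whether any gene fell within a cell type or with the mix of cells was not tested. Immediate-early genes rose for 11 of 20 and fell for 1 (14 and 1 adjusted over the list alone), and cell death genes for 13 and 3 of 29 (14 and 3), with adjusted p = 0.143 and adjusted p = 0.256 with an estimated correlation. Axon injury genes rose for 10 of 33 and fell for 1 (10 and 1), and antioxidant genes for 9 and 2 of 29 (9 and 3), with adjusted p = 0.145 and adjusted p = 0.676 with an estimated correlation. The mitochondrially encoded list rose for 6 of 9 members (9), with adjusted p = 0.476 with an estimated correlation, and pericyte and fibroblast markers for 7 of 16 (8), with adjusted p = 0.61 with an estimated correlation.

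In NeuN-negative nuclei 2650 genes were higher and 2220 lower among 17604 tested, and 3197 and 2258 without the 3 mice, where 69 of 73 interferon-stimulated genes were higher and 13 of 19 oligodendrocyte markers lower. The NeuN-negative libraries kept there held 2.177 to 7.944% mitochondrially encoded counts in EAE and 0.3673 to 2.03% in healthy mice, without overlap. That fit therefore does not part library quality from EAE either. The largest rises with over 3 counts in healthy mice included Saa3 (8.87 ± 1.04), Acod1, the itaconate enzyme gene of macrophages (8.29 ± 0.67), F7, a coagulation factor gene (7.93 ± 0.59), and Cxcl9 (7.93 ± 0.80). Glycolysis genes rose for 4 and fell for 3 of 24 (4 and 3; camera adjusted p = 0.893), among them Hk2 (2.27 ± 0.39), Ldha (2.29 ± 0.30) and Pfkfb2 (-1.63 ± 0.44). The mitochondrial share as a covariate left 1010 genes higher and 444 lower, and the oligodendrocyte marker level, which differed between the groups, left 242 and 8. Other tests called 7837 and 2892 (DESeq2 Wald) or 4517 and 4552 (limma voom). Leaving out a single library gave 1796 (without healthy 2) to 4011 (without healthy 3) genes higher and 1370 (without EAE 5) to 2806 (without EAE 3) lower.

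The other lists of the NeuN-negative comparison were not called by camera. Among uncalled lists, the signs of the median, the mean and the camera direction differed for glycolysis, inhibitory neuron, voltage-gated channel, stress response, transmitter receptor and Schwann cell genes. Standard proteasome genes rose for 1 of 34 and fell for 2 (1 and 0 adjusted over the list alone), and oxidative phosphorylation genes rose for 7 of 75 and fell for 3 (0 and 1). Pentose phosphate genes rose for 1 of 10 and fell for 0 (1 and 0), stress response genes for 3 and 3 of 33 (3 and 3) and heat shock genes for 1 and 2 of 14 (1 and 2). Voltage-gated channel genes rose for 5 of 41 and fell for 4 (3 and 4), transmitter receptor genes for 3 and 7 of 39 (3 and 7) and synaptic release genes for 2 and 5 of 33 (2 and 5). Neuron markers rose for 0 of 16 and fell for 1 (0 and 0), excitatory ones for 1 and 0 of 14 (0 and 0), inhibitory ones for 1 and 1 of 13 (1 and 1) and those of motor neurons for 3 and 2 of 13 (4 and 2). Endothelial markers rose for 2 of 16 and fell for 0 (1 and 0), ependymal ones for 2 and 1 of 12 (2 and 1), those of Schwann cells for 2 and 0 of 10 (1 and 0) and erythroid ones for 0 and 0 of 5 (0 and 0). Without the 3 mice the numbers higher and lower were 1 and 4 for channel, 1 and 7 for receptor, 4 and 1 for standard proteasome and 6 and 1 for microglia genes.

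**Figure D3:**
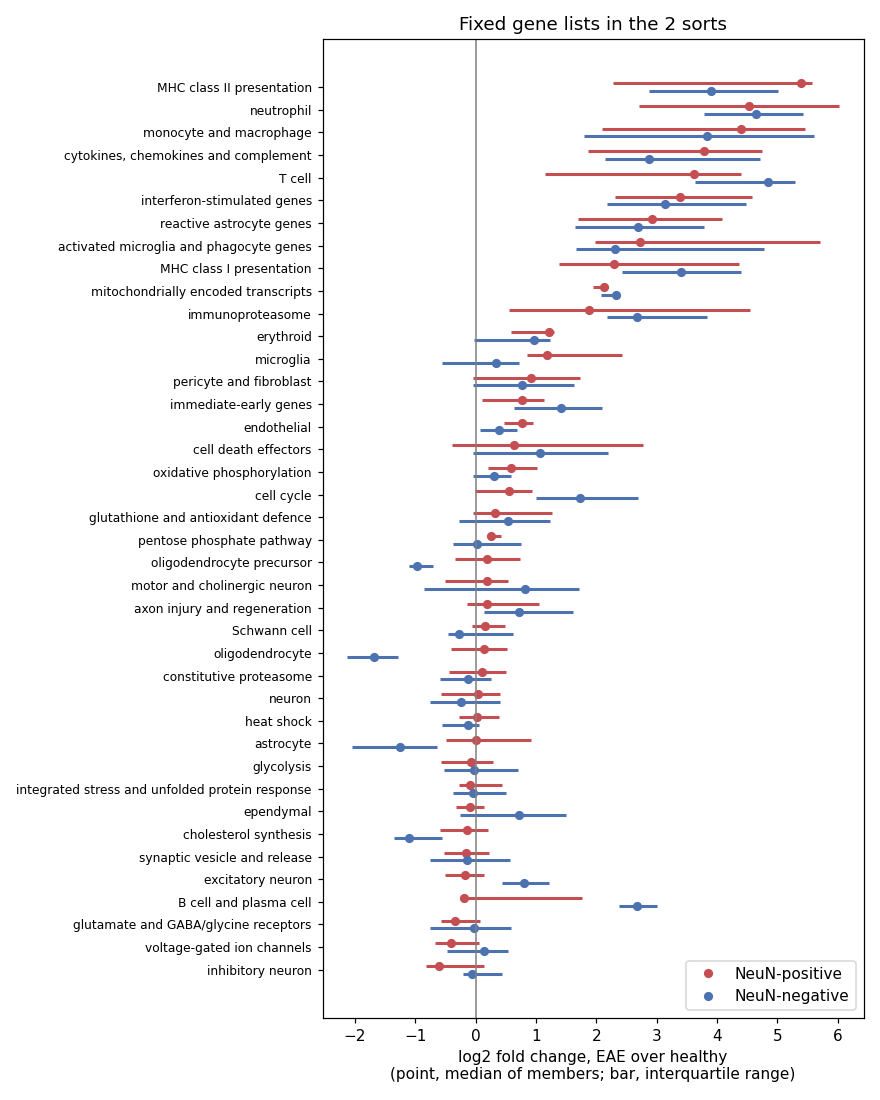
Median log2 fold change of EAE over healthy (x axis; bar, interquartile range of members) of the 40 gene lists (y axis) in NeuN-positive and NeuN-negative nuclei. The interferon-stimulated list had medians of 3.39 and 3.13, and the oligodendrocyte list 0.13 and -1.68.

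The EAE effects in the 2 sorts overlapped. Of 15837 genes tested in both, 764 were higher in both and 265 lower in both. The sorts are taken to come from the same mice, so an overlap above that of unrelated lists need not be a shared effect, and no expected number is given. Over these genes the log2 fold changes correlated at 0.63 (Pearson, across genes, which are not independent replicates). The interaction test, which asks whether the effect differs between the sorts, called 356 genes with a higher and 168 with a lower log2 fold change in NeuN-positive nuclei among 20444. Psmb9, Psmb8 and Psmb10 were not among them, with differences of 1.10 ± 0.61, 0.80 ± 0.57 and -0.68 ± 0.46 (adjusted p = 0.343, 0.478 and 0.45). Without the 3 mice the differences were 0.44, -0.05 and -1.38, and Psmb10 was called lower (adjusted p = 0.0401), with 2 of 5 genes of the immunoproteasome list lower and a list median of -1.23 against -0.68. The oligodendrocyte list differed most, with 6 of 19 genes called higher (15 adjusted over the list alone) and a median difference of 1.87, for example Opalin at 3.22 ± 0.56 and Mal, a myelin proteolipid gene, at 2.38 ± 0.57. By camera the astrocyte (2 of 16 genes called higher, 16 adjusted over the list alone), microglia (3 of 14, 5), cholesterol synthesis (2 of 24, 12) and oligodendrocyte precursor lists (1 of 11, 3) were higher too. These calls were lost with an estimated correlation. T cell markers were lower (3 of 21, 5 lower and 1 higher adjusted over the list alone), with Lck, a T cell kinase gene, at -3.24 ± 0.62. Camera also called the cell cycle (2 of 38 lower, 2), excitatory neuron (1 of 14, 1) and immediate-early lists (0 of 21, 1) lower. Of the 40 lists camera called 5 higher and 4 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.132. Among uncalled lists, the signs of the median, the mean and the camera direction differed for MHC class II, glycolysis, synaptic release, axon injury, B cell and ependymal genes.

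With the replicate block the interaction called 1992 genes higher and 500 lower, and without the 3 mice 363 and 362. There the numbers higher were oligodendrocyte 3 of 19, astrocyte 0 of 16, precursor 0 of 11, microglia 3 of 14 and cholesterol synthesis 3 of 23. The numbers lower were T cell 5 of 21, cell cycle 4 of 38, excitatory neuron 0 of 14 and immediate-early 3 of 22. DESeq2 size factors moved the median of all genes by -0.257 on the log2 scale and called 236 higher and 236 lower, so the share of higher calls went from 67.9 to 50%. Leaving out a single library gave 63 (without EAE NeuN-positive replicate 5) to 754 (without EAE NeuN-negative replicate 3) genes higher.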

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

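The tests of carry-over, dilution, GC content and library quality were chosen only after the results were seen, while those of genomic DNA, of a few receptor genes and of other splits of the libraries were set before their values were known. The bootstrap intervals given in brackets resampled the genes of a set, not the libraries. They treat genes as independent and do not measure the spread between libraries.

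Interferon-stimulated, MHC class I and immunoproteasome genes were higher in NeuN-positive libraries of EAE mice (76 called). Lower library quality as the whole account is argued against: with the mitochondrial share as a covariate the median log2 fold change of all 91 tested members was 2.94 (95% bootstrap interval 2.64 to 3.41) against 3.07, and 63 of the 76 were still called. Carry-over of RNA or nuclei from the NeuN-negative fraction, which the sort should remove, could account for it. The median rise over healthy mice was 29.3% of the level in NeuN-negative EAE libraries. Markers of 12 non-neuronal cell types were seen at 16.5 to 53.8% of theirs (microglia 19.2%, T cells 21.6%, monocytes and macrophages 29%, astrocytes 53.8%). The log2 difference to the highest was -0.88 (-2.31 to -0.69). This comparison is lenient, since the shares of microglia and T cells were below that of the pattern and astrocyte markers fell in NeuN-negative EAE libraries. The marker shares also had no healthy level taken off, which raises them against the rise of the pattern. The comparison therefore cannot decide for or against carry-over. Lyz2 of phagocytes reached 521 CPM in NeuN-positive EAE libraries, 6 of the 76 genes also belong to another list, and 53 were at 1 CPM or more in healthy NeuN-positive and 73 in healthy NeuN-negative libraries, so a response of the neurons themselves stays open as well.

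Genes lower in NeuN-positive libraries of EAE mice (613) had a median log2 fold change of -1.26, which selection makes larger. Dilution of neuronal RNA by other nuclei stays open. The 1413 genes at least 4-fold higher in NeuN-positive libraries of healthy mice had a median of -0.35 (-0.39 to -0.32), a fall as well. It is smaller than -1.26, but that value comes from genes picked for falling. TMM can also take up an even dilution, so the comparison cannot decide. Of the 613 genes, 321 were called higher and 52 lower in NeuN-positive than in NeuN-negative libraries of healthy mice. That comparison shares the healthy NeuN-positive libraries with this one. GC content as the whole account is argued against, since 471 of the 613 were still called with each library's GC trend removed. Lower quality and EAE cannot be told apart for this pattern: without the 3 mice with a high mitochondrial share the median was -1.02 (-1.06 to -0.97, with 234 still called and a median standard error of 0.30 against 0.32). With that share as a covariate 116 were still called, with a median of -1.0 and a median standard error of 0.34, so calls ended with a smaller fold and a similar spread. The share itself had a higher mean in EAE libraries, 3.61 against 0.910%, so the covariate can take part of an EAE effect with it, and an effect of the disease on neurons stays open, untested.

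Counts of olfactory and vomeronasal receptor genes, expressed in sensory epithelia, reached 2310 and 1960 CPM in NeuN-negative EAE libraries 2 and 4, against 184 to 484 in the other 3. A few expressed receptor genes are argued against, since the 10 with most counts held 4.59% of the receptor counts of these libraries. Genomic DNA in the libraries may contribute, since keratin-associated, beta-defensin and taste receptor genes were 5.48-fold higher in the same libraries. Mean receptor counts were also higher in EAE than in healthy libraries of both sorts. They were 159.2 against 39.7 CPM in NeuN-positive and 1025 against 100.8 CPM in NeuN-negative libraries. Gm10800 and Gm10801 took 1.231 against 0.1461% and 9.384 against 0.8432% of counts. The groups overlapped only through healthy replicate 3. None of these differences passed adjustment, with unadjusted p of 0.0159 to 0.0317 (exact permutation tests, two-sided). The other healthy libraries reached 36.6 CPM (NeuN-positive) and 97.1 CPM (NeuN-negative) for receptor genes, against lowest EAE values of 54 and 184 CPM. For Gm10800 and Gm10801 they reached 0.1233 and 0.7219%, against lowest EAE values of 0.3307 and 1.672%. Whether genomic DNA adds to the genes called higher in EAE was not tested. No other biological explanation was tested.

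Other splits of the libraries were drawn 100 times for each comparison, the real one included. In NeuN-positive nuclei the real split called 1705 genes and 2 of the 100 splits called as many, a share under 0.05, while 98 called 0. That share argues against a random grouping of the libraries only. It cannot part an effect of EAE from one of library quality. The highest other split, with 2266 genes, called more than the real one. It set EAE 1, 2, 4 and 5 with healthy 3 against EAE 3 with healthy 1, 2, 4 and 5, which follows library quality (mean mitochondrial share 3.97 against 0.552%) as well as most of the EAE labels. In NeuN-negative nuclei the real split called 4870 and 1 of 100 as many, and the highest other, with 1685, joined the same numbers (8.36 against 1.32%). The interaction called 524 (1 of 100, highest other 0). Its other splits mixed EAE and healthy mice on each side, which adds the EAE effect to the spread. That share therefore cannot decide on chance for the difference between the sorts. The sorts of healthy mice called 7848 (1 of 100, highest other 0). Those of EAE mice called 5455 (1 of 100, highest other 659, and 1 among splits that part all 5 pairs). The sorts are taken as paired, and only 13 of the splits of each sort comparison part all 5 pairs. These are too few for a share under 0.05, so chance is not excluded for the sorts. A swap of EAE 3 and healthy 3 is not borne out by Psmb9, at 39.2 CPM in the NeuN-positive library labelled EAE 3 and 1.19 CPM in that labelled healthy 3.

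Of 216 sets of 5 libraries, 16 had a library far from the others by Dixon's ratio, where chance gives about 1 in 20. Healthy replicate 3 accounts for 10. In NeuN-positive nuclei these were the mitochondrial share (ratio 0.773), Gm10800 and Gm10801 (0.796), the 10 most abundant genes (0.758), receptor genes (0.81) and the low standard proteasome level (0.767). In NeuN-negative nuclei they were Gm10800 and Gm10801 (0.792), the 10 most abundant genes (0.737), receptor genes (0.746), and low standard proteasome (0.83) and glycolysis levels (0.877). Healthy NeuN-negative replicate 5 was high in motor neuron markers (0.848). EAE NeuN-negative replicate 1 was high in oxidative phosphorylation (0.72), astrocyte (0.792) and endothelial genes (0.732), and replicate 3 low in cell cycle (0.761) and high in B cell genes (0.764).

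The interaction test found 9 lists and 37 named genes with a different EAE effect in the 2 sorts, given as NeuN-positive minus NeuN-negative on the log2 scale. The list medians (without the 3 mice in brackets) were oligodendrocyte 1.87 (1.37), astrocyte 1.71 (1.31), microglia 1.40 (1.22), cholesterol synthesis 1.15 (0.81), oligodendrocyte precursor 1.07 (0.69), immediate-early -0.47 (-1.17), cell cycle -0.52 (-0.82), T cell -0.92 (-1.05) and excitatory neuron -0.95 (-0.76). With an estimated correlation 0 of the 9 were called (lowest adjusted p = 0.132), and 28 of the 37 genes lost their call in 1 or more alternatives, among them Gfap in 21 of 27, Atp13a4 in 20, Vldlr in 19 and Tyrobp and Ccne1 in 18 each. Higher were Cysltr1 5.74 (with 2 counts over the healthy NeuN-positive libraries, so that its size rests on the prior count), Sash3 3.41, Olfml1 3.26, Opalin 3.22, Ccl22 3.01, Trem2 2.74, Selplg 2.56, Pdgfra 2.48, Mal 2.38, Gabra2 2.36, Xaf1 2.28, Tyrobp 2.24, Stmn4 2.12, C1qc 2.11, Cacnb4 2.07, Tmem119 2.01, Dhcr7 1.83, Gfap 1.80, Atp13a4 1.78, Msmo1 1.74, Gria4 1.73 and Vldlr 1.71. Lower were Fpr2 -5.25, Tlr9 -5.16, Cntn5 -5.12, Hpse -4.97, Fstl4 -4.95, Dnah11 -3.50, Lck -3.24, Skap1 -3.09, Socs1 -2.90, H2-DMa -2.18, Ccne1 -1.97, Birc5 -1.91, Lmx1b -1.84, H6pd -1.82 and Cacna1d -1.58.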

How the results depend on the processing

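The fits with the mitochondrial share as a covariate, without the EAE 2, EAE 4 and healthy 3 mice, with the GC trend removed and without Gm10800, Gm10801 and mitochondrial genes were chosen only after the data were seen. Where a count changed, the cause was not tested unless stated. Pairs of counts are genes higher and lower.

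In NeuN-positive nuclei (1092 and 613) the DESeq2 Wald test called 2634 and 1412 and voom 3823 and 3882. The oligodendrocyte covariate gave 982 lower, the mitochondrial covariate 528 and 166, and the fit without the 3 mice 317 lower, with fewer samples. The replicate block, which has no pairs to follow between EAE and healthy mice, gave 738 and 411.

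In NeuN-negative nuclei (2650 and 2220) the Wald test called 7837 higher, voom 4517 and 4552, no filter 5618 higher, and all 20 libraries in a single fit 3786 lower. The mitochondrial covariate left 1010 and 444, and the replicate block 1877 and 1800. The oligodendrocyte covariate left 242 and 8 and changed the sign of 1876 of the called genes. That covariate itself differed between the groups, as 13 of 19 of these markers fell in EAE.

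For the difference between the sorts (356 and 168), DESeq2 size factors called 236 higher, the Wald test 672 and 960, voom 3066 and 1864, no filter 183 and 85 with more genes tested, the replicate block 1992 and 500, and the fit without the 3 mice 362 lower. Between the sorts, voom called 6201 and 6018 in healthy mice. In EAE mice the Wald test called 6905 lower and voom 4550 and 4596. Other planned and added alternatives stayed within 1.5 times of each count, and the mitochondrial share without the 10 most abundant genes moved by less than 1 SD in each group.

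With an estimated correlation, which widens the spread assumed for a list, 8 lists were higher and 0 lower in NeuN-positive nuclei and 11 and 1 in NeuN-negative nuclei. There were 0 and 0 for the difference between the sorts, 0 and 2 for the sorts of healthy mice and 0 and 0 for those of EAE mice. The replicate block ended the calls of Dnah11 for the difference between the sorts (-2.63, adjusted p = 0.0743) and of Grm3 (-1.56, 0.0593) and Gabrb2 (-1.90, 0.0787) between the sorts of EAE mice, where Pfkfb3 was called lower (-0.70, 0.0257). In NeuN-negative nuclei of EAE against healthy mice it ended the calls of the antioxidant (adjusted p = 0.0369 to 0.059) and the pericyte and fibroblast lists (0.0378 to 0.0748). Between the sorts and for their difference it changed no other call of a named gene and no list call other than those given in the report.

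Leaving out a single library gave 677 (without healthy 2) to 1721 (without healthy 3) genes higher in NeuN-positive nuclei, and 1662 without EAE 3. It gave 178 (without EAE 5) to 1462 (without EAE 3) lower. The other counts lower were 201, 364 and 302 without EAE 1, 2 and 4, and 245, 201, 998 and 284 without healthy 1, 2, 3 and 4. In NeuN-negative nuclei it gave 1796 (without healthy 2) to 4011 (without healthy 3) higher and 1370 (without EAE 5) to 2806 (without EAE 3) lower, with 1381 without EAE 4.

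For the difference between the sorts the range was 63 (without EAE NeuN-positive 5) to 754 (without EAE NeuN-negative 3) higher and 21 (without healthy NeuN-negative 2) to 353 (without healthy NeuN-negative 3) lower. The counts without a NeuN-positive library were 143 and 46 (EAE 1), 135 higher (EAE 2), 86 and 76 (EAE 4), 62 lower (EAE 5), 93 and 49 (healthy 1), 71 and 32 (healthy 2), 219 and 71 (healthy 4) and 183 and 78 (healthy 5). Without a NeuN-negative library they were 228 higher (EAE 2), 279 lower (EAE 3), 149 and 82 (EAE 4), 135 and 48 (healthy 1), 72 higher (healthy 2), 222 higher (healthy 3) and 170 and 61 (healthy 4). The sorts of healthy mice gave 3503 to 4354 higher (without healthy NeuN-negative 2 and 3) and 3471 to 4300 lower (without healthy NeuN-positive 2 and NeuN-negative 3). Those of EAE mice gave 2202 to 3237 higher and 1731 to 3482 lower, each without EAE NeuN-positive 5 and 2.

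Of the called named genes 47 of 89 in NeuN-positive nuclei, 35 of 113 in NeuN-negative nuclei and 9 of 37 for the difference between the sorts kept their call and sign in every alternative. Of the 94 named genes of NeuN-positive nuclei, 94 stayed called or uncalled as before with DESeq2 size factors, 74 without the 3 mice and 58 with the mitochondrial covariate. Of the called genes 0 changed sign. These numbers take no account of the sign of uncalled genes. Without the 3 mice the uncalled Psmb6 (-0.10), Psmb7 (-0.30) and Pfkfb3 (0.13) had the opposite sign. Of the 118 of NeuN-negative nuclei these numbers were 118, 110 and 70. Without the 3 mice the uncalled Psmb7 (-0.18) and Pfkfb3 (0.29) had the opposite sign there. In NeuN-negative nuclei 27 called genes changed sign with the oligodendrocyte covariate. Their log2 fold changes were Pfkfb2 1.30, Insig1 0.99, Mir219a-2 0.98, Adam1a 0.76, Psat1 0.71, Vldlr 0.65, Psmd6 0.57, Il18 0.52, Cacnb4 0.43, Fa2h 0.43, Gstp1 0.36, Hsph1 0.26, Dnajb1 0.24 and Psmc4 0.13. The others were Scn9a -0.05, Atf5 -0.23, Cox6a1 -0.25, mt-Nd6 -0.98, Gldn -1.45, Unc13c -1.75, Dnah11 -1.77, Sv2c -1.84, Grin2a -1.94, Hydin -2.28, mt-Nd5 -2.42, Gabrb2 -2.49 and Kcnb2 -2.57. With the mitochondrial covariate 3 called genes changed sign, Sv2c (-0.26), Kcnb2 (-0.20) and Unc13c (-0.15).

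The stricter filter and the omission of mitochondrial genes gave no value for named genes they removed, and the covariates were not fitted for the difference between the sorts or for the sorts. The fewest counts were in NeuN-negative EAE replicates 2 and 4, with 3149209 and 4104125, and what depth limits was not tested. Pfkfb3, uncalled between the sorts of EAE mice, was called lower in 4 alternatives, with -0.93 without EAE 2 and 4 (adjusted p = 0.0133), and Psmb10 in 2, with -1.28 (0.00108).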

Other observations

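The genes in this part were chosen after their values were seen, and no test was set for them in advance.

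In NeuN-negative nuclei of EAE mice 13 of 19 oligodendrocyte markers fell and 0 rose. Mog, a surface myelin glycoprotein gene, and Cnp, a myelin enzyme gene, fell by 2.45 ± 0.53 and 1.30 ± 0.37 on the log2 scale (edgeR quasi-likelihood test, adjusted p = 0.0032 and 0.0162). The myelin genes Mbp and Mobp had log2 fold changes of 1.11 ± 0.73 and 1.79 ± 0.70 and were not called (adjusted p = 0.262 and 0.065). The difference between these genes was not tested.

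Mbp also varied widely within groups. In healthy NeuN-positive libraries it was at 30940 CPM in replicate 3 and at 1842 to 7204 CPM in the other 4, and in EAE NeuN-positive libraries at 57420 and 27770 CPM in replicates 2 and 4 and at 5569 to 6975 CPM in the other 3. These 3 high libraries are those with over 2% mitochondrially encoded counts (3.003, 9.347 and 5.3%).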
